A study of Mus musculus with 3 samples.

How the data were processed

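The series holds 3 expression arrays of 1 group. Per the labels, each array was hybridised with biotin-labelled total RNA from neurospheres, floating colonies grown from single precursor cells. The cells came from the ventricular-subventricular zone (V-SVZ), the stem cell region along the lateral ventricles, of wild-type CD1 mice at postnatal day 8 (the growth protocol allows day 7 or 8). They were plated at 10 cells per microlitre and kept for 7 days with 10 ng/ml FGF and 20 ng/ml EGF. The protocol states that pups were kept in separate cultures. Whether each array holds 1 pup is not given in the sources used here. The p-values of single genes therefore rest only on the spread between these 3 arrays, which may be technical. In the detection test described below this spread is pooled over genes of like signal. Fisher's exact tests of gene lists compare genes and measure no spread between arrays.

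The values are log2 signals that the authors deposited for 41345 probe sets, made with RMA per the submitters' processing notes. RMA corrects background, normalises arrays between each other and summarises the probes of a set. Its version and options, and the probe-level files, were not used here. Genes were named from the array's annotation table. Of the probe sets, 23521 carried 1 gene symbol, 1814 carried several and 16010 carried none. Only those with 1 symbol were given a gene name, which left 22180 genes. For the 1082 genes with several probe sets, the probe set with the highest mean signal was used. No genome was used, so no coordinates are given. Signals of different genes were not ranked against each other, because probes bind with different strength. For arrays, the number of samples limits the precision, here n = 3.

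With no second group there is no contrast, so each gene was set against the unspecific signal of its own array. The reference level was the 95th percentile of 1400 probe sets of olfactory and vomeronasal receptors, genes of the sensory epithelia of the nose. A gene was called above the reference level when limma's one-sided moderated test (an intercept, eBayes with an intensity trend) gave an adjusted p under 0.05 (Benjamini-Hochberg over all 22180 genes). The prior degrees of freedom of that fit were infinite, so all genes of like signal shared 1 spread. A gene's own spread had no weight in its p-value, and margins as small as 0.15 on the log2 scale passed. A call therefore says that a signal exceeded the reference level, and very small p-values are not printed.

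There were 33 gene lists with 570 different members, fixed before the data were examined, of which 512 were measured. The other members had no probe set with that symbol alone among the values used here and were not analysed here. Each list was compared with all other genes, receptors left out, by a two-sided Fisher's exact test adjusted over the 33 lists, and 10 planned pairs of lists were compared by the same test after shared members were left out. Genes are not independent replicates, so these tests describe the lists on these arrays. The count of members above the reference level adjusted over the list alone equalled the count adjusted over all genes in each of the 33 lists. The text names up to 6 members above and 6 not above per list, in the order written, all members of the 4E-T and sex-linked lists, and the 20 genes with the largest variance ratio. Genes named outside that rule are marked as chosen after their values were seen.

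Differences between the 3 arrays were tested per gene by limma's residual variance over its trended prior variance (F test), and per list by the SD of the list mean against 10000 random lists of like signal. The steps were tested on simulated data with 22180 genes. The detection test recovered 30 of 50 genes set 0.25 log2 units above the reference level and 49 of 50 at 0.5. It made 0 false calls among 5511 unchanged genes. These had been set at least 0.5 log2 units under the lowest reference level, so false calls near the level were not tested. The variance test recovered 44 of 67 changes of 1 log2 unit in simulated noise, and 0 of 67 when the same change was added to the deposited values, over 14158 genes.

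Alternatives changed the reference percentile to 90 or 99, the reference genes to keratin-associated proteins, defensins and bitter taste receptors (139 probe sets), the choice of probe set, the scaling between arrays and the model, and left out each replicate in turn. R 4.3.3 with limma 3.58.1 was used, and matplotlib 3.10.9 for the figures.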

Results

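Gene expression was measured on 3 arrays of neurospheres grown from the V-SVZ of wild-type CD1 mice at postnatal day 8, all of 1 group, so the data show which genes these cultures expressed and how far the 3 arrays differed. The array medians were 5.87, 5.85 and 5.86 on the log2 scale, and the reference levels set by olfactory and vomeronasal receptors were 5.63, 5.53 and 5.71. Of 22180 genes, 13102 (59.1%) were above the reference level. Among the receptor genes themselves it was 54 of 1390 (3.88%), and among the other genes 13048 of 20790 (62.8%), which is the share each gene list is set against. Signals are given as mean log2 ± SD with n = 3. Many probe sets held exactly equal values on several arrays, so an SD of 0 or near it understates the true spread.

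The series is named for the translational repressor 4E-T, and the first question was whether the cultures expressed it and its partners. Eif4enif1, which encodes 4E-T, a protein that binds the cap-binding factor eIF4E, had a signal of 8.81 ± 0.085, with 8.82, 8.89 and 8.72 on the 3 arrays, and was above the reference level on each. Of 32 measured genes of the cap-binding, translational repression and mRNA decay list, 31 were above the reference level, against 62.7% of other genes (Fisher's exact test, adjusted p = 1.56e-04). The cap-binding genes Eif4e (10.66 ± 0.033) and Eif4e2 (9.62 ± 0.029) were among them, as was Ddx6 (11.36 on every array), a helicase of the cytoplasmic granules called P-bodies. Nanos2, a germ cell RNA-binding factor, was the only measured member not above the reference level, at 5.51 ± 0.10.

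RNA-binding partners and decay enzymes were measured across the list. The P-body components Lsm14a (9.29 ± 0.060), Lsm14b (8.98 ± 0.084), Patl1 (9.87 ± 0.080) and Edc3 (8.31 ± 0.017) were above the reference level, as were Edc4 (9.18 ± 0.054), the decapping genes Dcp1a (9.42), Dcp1b (7.69) and Dcp2 (8.90), the exonuclease gene Xrn1 (9.07) and the deadenylase gene Cnot7 (9.11). Among sequence-specific repressors, Pum2 had 10.06, Samd4 7.10, Samd4b 10.03, Zfp36l1 10.52, Nanos1 7.15, Cpeb2 9.64, Cpeb4 9.71 and Cpeb1 6.20. The RNA transport genes Stau1 (10.16), Stau2 (7.82) and Fmr1 (9.85), the microRNA pathway genes Ago2 (10.09) and Tnrc6a (9.70), and the eIF4E-binding repressors Eif4ebp1 (9.15) and Eif4ebp2 (9.73) were also above. Eif4e3 (5.80 ± 0.22, limma adjusted p = 0.0209) and Nanos3 (5.88, limma adjusted p = 0.00111) lay close to the reference level. Eif4e3 had 5.67, 6.05 and 5.67 on arrays 1, 2 and 3, and on array 3 it was under the reference level of 5.71. Its p-value rests on the shared spread, while its own margin over the reference level was 0.17 ± 0.30. The calls of Eif4e3, Nanos3 and Cpeb1 ended when the reference was taken as the 99th percentile of the receptors.

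Neural stem cell genes were expressed broadly. Of 20 stem cell and radial glia markers, 19 were above the reference level (adjusted p = 0.00379), including the transcription factor gene Sox2 (11.39 ± 0.073), the intermediate filament genes Nes (8.50 ± 0.035) and Vim (13.49), and Fabp7 (13.73), the brain lipid-binding protein of radial glia. Fut4 had 5.40 and was not above. Of 20 genes described as higher in quiescent stem cells, 19 were also above (adjusted p = 0.00379), among them Id2 (12.69), Id3 (9.64), Vcam1 (10.89) and Aldoc (12.82), while Thbs4 (5.34) was not. All 14 measured markers of activated stem cells and transit-amplifying precursors were above (adjusted p = 0.00379), including Dlx2 (9.87 ± 0.046), Gsx2 (7.31), Egfr (11.42) and the Notch ligand genes Dll1 (9.28) and Dll3 (9.53). With only the members that stand in no other list, chosen after the data were seen, the stem cell list had 12 of 13 above (adjusted p = 0.0589) and the transit-amplifying list 4 of 4 (adjusted p = 0.358).

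Cell cycle genes and their inhibitors were detected together. All 19 measured DNA replication genes (adjusted p = 0.00118) and all 21 genes of G2 and M phase (adjusted p = 9.06e-04) were above the reference level, for example the replicative helicase genes Mcm2 (8.73) and Mcm4 (9.55 ± 0.024), the proliferation marker Mki67 (10.29), Top2a (9.52) and Cdk1 (10.13). All 15 measured cell cycle inhibitors were above as well (adjusted p = 0.00379), including Cdkn1a (10.51), Cdkn1b (10.77), Cdkn1c (7.53 ± 0.11) and Cdkn2a (6.75). The call of Cdkn2a ended with the 99th percentile as the reference. RNA from whole cultures does not show whether the same cells held both kinds of transcript.

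Receptors for the growth factors in the medium were expressed. Of 20 growth factor receptor and feedback genes, 19 were above the reference level (adjusted p = 0.00379), with Egfr at 11.42, Erbb4 at 11.05 ± 0.038, Fgfr1 at 9.50 and Fgfr2 at 10.74, while Met, the hepatocyte growth factor receptor gene, was not above at 5.61. Of 20 Notch pathway genes, 19 were above (adjusted p = 0.00379), including Notch1 (10.96), Notch2 (9.63) and Notch3 (8.84), and the ligand gene Dll4 (5.27) was not. Of 23 genes of Shh, Wnt and BMP signalling, 21 were above (adjusted p = 0.00688), including Ptch1 (10.21), Smo (10.41), Gli2 (7.65) and Gli3 (9.01). Gli1 (4.81 ± 0.069), a Shh pathway factor, and Lef1 (5.50 ± 0.061), a Wnt pathway factor, were not. The Notch list was no longer different from other genes with the 99th percentile as the reference (70% above, adjusted p = 0.101).

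**Figure D1:**
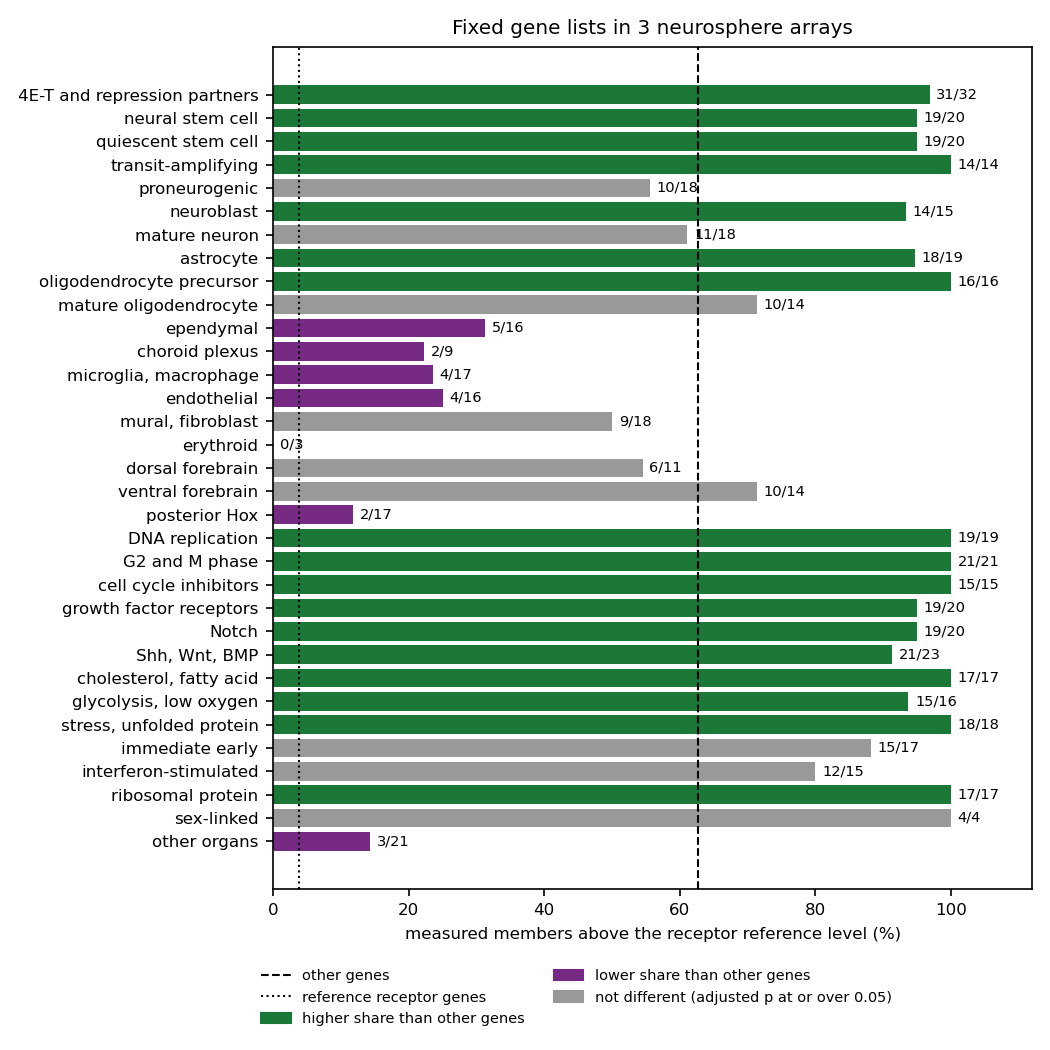
Percent of the measured members of each fixed gene list above the receptor reference level (horizontal axis), with the number above over the number measured beside each bar; green and purple bars mark lists above or below other genes by Fisher's exact test. The dashed line marks the 62.8% of other genes and the dotted line the 3.88% of receptor genes, a share set by construction. Of the lists, 17 lie above the other genes and 6 below.

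The next comparison asked how far transcripts of the neuronal lineage were present. Of 15 neuroblast markers, 14 were above the reference level (adjusted p = 0.0221), including Dcx (9.90), a microtubule protein gene of migrating neuroblasts, Tubb3 (9.22 ± 0.066) and Dlx5 (7.98 ± 0.068), and Sp8 (5.11) was not. Of 18 measured genes of the neurogenic programme, 10 were above, no different from other genes (adjusted p = 0.646). Sox4 (11.23), Sox11 (8.61 ± 0.092), Neurog2 (7.52 ± 0.083) and Neurod2 (6.72) were above, while Neurog1 (5.40 ± 0.063), Neurod1 (5.07 ± 0.18), Eomes (5.58 ± 0.072) and Tbr1 (4.77) were not. The call of Neurod2 ended at the 99th percentile. Of 18 mature neuron markers, 11 were above (adjusted p = 1), with Map2 (11.98) and Snap25 (8.57) above, and the vesicular glutamate transporter gene Slc17a7 (5.13 ± 0.16) and the neurofilament genes Nefl (5.58) and Nefm (5.31) not above.

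List against list, a larger share of stem cell markers (95%) than of mature neuron markers (61.1%) was above the reference level (Fisher's exact test, adjusted p = 0.0268). Transit-amplifying markers (13 of 13) exceeded neurogenic programme genes (9 of 17) in the same way (adjusted p = 0.00875, 1 shared gene, Insm1, left out). Neuroblast markers and mature neuron markers did not differ after adjustment (adjusted p = 0.0515). With the 90th percentile as the reference the first pair had adjusted p = 0.0829 and the second 0.0874, and the neuroblast list alone was no longer different from other genes (adjusted p = 0.138), as it also was at the 99th percentile (66.7% above, adjusted p = 0.249). The neuroblast pair passed without replicate 1 (adjusted p = 0.0117), without replicate 3 (adjusted p = 0.0268) and with the median over a gene's probe sets (adjusted p = 0.0117).

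Glial lineage genes were expressed in the same cultures. Of 19 astrocyte markers, 18 were above the reference level (adjusted p = 0.00572), including Gfap (12.91), the water channel gene Aqp4 (12.44), Aldh1l1 (11.42) and Slc1a3 (12.60 ± 0.025), with the connexin gene Gjb6 (5.11) not above. All 16 oligodendrocyte precursor markers were above (adjusted p = 0.00364), including Pdgfra (10.97), Olig1 (12.36 ± 0.036), Olig2 (11.37) and Sox10 (10.26 ± 0.026). Of 14 mature oligodendrocyte markers, 10 were above (adjusted p = 0.629). Among them were the myelin genes Mbp (8.72 ± 0.029) and Cnp (10.78 ± 0.097) and the myelination factor gene Myrf (10.33), while Mobp (5.58 ± 0.068), Opalin (5.31), Ermn (4.52 ± 0.086) and Gjb1 (5.30) were not.

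The share above was larger for oligodendrocyte precursor markers than for mature oligodendrocyte markers (adjusted p = 0.0457), for astrocyte than for mature neuron markers (adjusted p = 0.0268) and for astrocyte than for ependymal markers (adjusted p = 5.40e-04). These 3 differences did not pass with the 90th percentile as the reference (adjusted p = 0.128, 0.225 and 0.0796). The astrocyte list shares genes with the stem cell lists. With members in no other list, 11 of 12 astrocyte markers were above (adjusted p = 0.0589).

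Markers of other cell types that V-SVZ tissue could bring were compared with other genes in the same way, and 4 of these lists had a smaller share above the reference level. Of 16 ependymal markers 5 were above (adjusted p = 0.0238), among them the ciliogenesis regulator gene Foxj1 (7.86 ± 0.024) and Ccdc153 (6.59 ± 0.18), while the ciliary genes Dnah5 (5.56), Rsph1 (5.66) and Hydin (5.40) were not. Of 17 microglia and macrophage markers 4 were above (adjusted p = 0.00379), namely Cx3cr1 (6.66 ± 0.27), C1qa (6.12), P2ry12 (6.05 ± 0.16) and Cd68 (6.43), and Csf1r (5.55) and Aif1 (4.73 ± 0.27) were not. Of 16 endothelial markers 4 were above (adjusted p = 0.00572): Kdr (6.84 ± 0.064), Itm2a (8.75), Egfl7 (5.83) and Slc2a1 (9.94), the last being a glucose transporter gene used by many cell types. Of 9 choroid plexus markers, Otx2 (8.27) and Ttr (6.20) were above (adjusted p = 0.0238). The mural and fibroblast list had 9 of 18 members above (adjusted p = 0.388), including Pdgfrb (6.99 ± 0.11) and Acta2 (7.45). Its members Pdgfra (10.97) and Cspg4 (8.15) also stand in the oligodendrocyte precursor list. With members in no other list, chosen after the data were seen, 6 of 15 were above (Fisher's exact test, adjusted p = 0.139). Of 3 measured red blood cell markers 0 were above (adjusted p = 0.0681), with Slc4a1 at 5.71 ± 0.18, Epb42 at 5.04 and Klf1 at 5.63. The stem cell list exceeded the microglia list (adjusted p = 7.13e-05).

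As a yardstick for absent cell types, 3 of 21 genes of liver, muscle, pancreas, testis and intestine were above the reference level (adjusted p = 1.56e-04): Apoa1 (5.87), Cela1 (5.95) and Tnnt3 (6.67), while the albumin gene Alb (4.60) and Ins2 (5.27) were not. In 8 pairs chosen after the data were seen, the microglia list (adjusted p = 0.774), the endothelial list (0.70), the ependymal list (0.508), the choroid plexus list (0.774), the mural list (0.0922) and the posterior Hox list (1) did not differ from this yardstick by Fisher's exact test. The mature neuron list (61.1% against 14.3% above, adjusted p = 0.0133) and the interferon list (80% above, adjusted p = 9.80e-04) did. These lists are small and the intervals wide. The odds ratio was 5.71 for the mural list (50% above, interval 1.08 to 41.1), counting its genes shared with the oligodendrocyte precursor list. It was 1.82 for the microglia list (interval 0.258 to 14.6) and 0.805 for the Hox list (0.0598 to 8.02). A lack of difference from the yardstick therefore does not show that such cells were absent. With the 90th percentile as the reference the ependymal, choroid plexus, microglia and endothelial lists no longer differed from other genes, with adjusted p of 0.663, 0.203, 0.0993 and 0.151. At the 99th percentile the calls of the 4 microglia markers, the 3 genes of other organs and Ttr, Egfl7 and Ccdc153 ended. The choroid plexus list did not then differ from other genes (adjusted p = 0.0637). The end of a call does not place a signal under that level. Cx3cr1 had 6.64, 6.39 and 6.93 on arrays 1, 2 and 3, where the 99th percentile was 6.42, 6.09 and 6.69. Ccdc153 also exceeded it on each array.

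**Figure D2:**
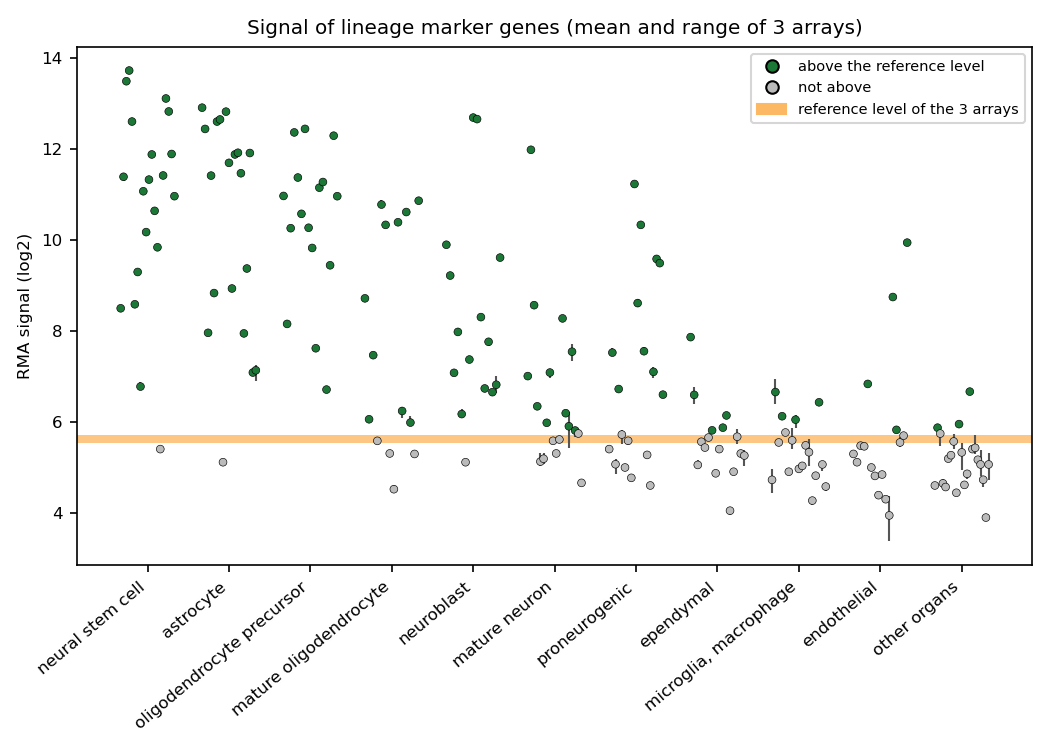
RMA signal on the log2 scale (vertical axis) of the measured members of 11 gene lists (horizontal axis, members in list order); each point is a gene's mean and each thin line the range over the 3 arrays. Green points are above the reference level, whose span over the arrays, 5.53 to 5.71, is the orange band; 16 of 16 oligodendrocyte precursor markers and 3 of 21 genes of other organs are green.

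Regional identity was compared with markers of the dorsal and the ventral forebrain. Of 11 dorsal markers 6 were above the reference level, including Emx2 (8.34 ± 0.14), Pax6 (9.30 ± 0.045) and Lhx2 (9.09), while Emx1 (5.47) and Tfap2c (4.70) were not. Of 14 ventral markers 10 were above, including Gsx2 (7.31), Dlx2 (9.87 ± 0.046), Nkx6-2 (7.32) and Six3 (7.20), while Nkx2-1 (5.67 ± 0.046), Isl1 (5.58) and Lhx8 (4.56 ± 0.25) were not. Neither list differed from other genes (adjusted p = 0.627 and 0.629), nor from the other by Fisher's exact test (odds ratio 0.495, interval 0.0667 to 3.36, adjusted p = 0.434). Posterior Hox genes, which mark hindbrain and spinal cord, were above in 2 of 17 cases (adjusted p = 2.31e-04), Hoxd8 (5.93 ± 0.18) and Hoxd10 (6.21 ± 0.13), a smaller share than of ventral forebrain markers (adjusted p = 0.00263). The calls of both Hox genes ended at the 99th percentile.

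Genes of lipid synthesis, translation and glycolysis were detected. All 17 measured genes of cholesterol and fatty acid synthesis were above the reference level (adjusted p = 0.00226), including Hmgcs1 (12.15), Fdft1 (11.87) and Sqle (10.58). All 17 ribosomal protein genes (adjusted p = 0.00226), such as Rpl4 (13.02) and Rpl8 (10.88), and 15 of 16 genes of glycolysis and low oxygen (adjusted p = 0.0140), such as Gapdh (13.10) and Pgk1 (12.02), were above, with the carbonic anhydrase gene Car9 (5.53 ± 0.085) not above. The glycolysis list had adjusted p = 0.0538 without replicate 2, and 0.0543 with the median over a gene's probe sets.

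Stress and signalling response genes were also present. All 18 genes of the unfolded protein and amino acid responses were above (adjusted p = 0.00170), including Atf4 (8.19), Ddit3 (7.78 ± 0.079), the asparagine synthetase gene Asns (11.38) and Chac1 (7.37). Of 17 immediate early genes 15 were above (adjusted p = 0.0567), with Fos at 8.09 ± 0.052, Jun at 10.33 ± 0.088 and Egr1 at 7.73, and Fosb (5.20 ± 0.21) and Ier2 (5.12) not above. Of 15 interferon-stimulated genes 12 were above (adjusted p = 0.245), among them Irf9 (7.89 ± 0.15) and Stat2 (7.95 ± 0.089), and Isg15 (4.93 ± 0.11), Mx1 (4.32 ± 0.25) and Bst2 (4.84 ± 0.12) were not. The immediate early list passed without replicate 1 (adjusted p = 0.0328), without replicate 2 (0.0376) and with the median over probe sets (0.0381). The interferon list fell to 33.3% above at the 99th percentile, where Ifit1, Ifit2, Ifit3 and Irf7 were no longer above.

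Xist and Y-linked genes were both detected on each array. Xist, the RNA that coats the inactive X chromosome of female cells, had 11.06 ± 0.022, with 11.05, 11.09 and 11.05 on the 3 arrays. The Y-linked genes Eif2s3y (9.38 ± 0.018), Kdm5d (9.37 ± 0.11) and Uty (9.23 ± 0.015) were above the reference level too, so that 4 of 4 measured genes of the list were above (adjusted p = 0.372 against other genes).

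The last comparison was between the 3 arrays, numbered here as cultures 1 to 3. Their differences may be technical, since whether each array holds 1 pup is not given. Across the 22180 genes of each pair of arrays, Pearson's r was 0.998 for cultures 1 and 2, 0.998 for 1 and 3 and 0.996 for 2 and 3, with SDs of the log2 difference of 0.15, 0.13 and 0.21, and Spearman's rho was 0.997, 0.998 and 0.995. These are correlations across genes, which are not independent replicates. Exactly equal values on 2 or 3 arrays were found for 16646 genes (75%). Of genes above the reference level, 38 (0.290%) had a range over 1 log2 unit, the widest being Phf11a (6.85, 5.40 and 7.18; range 1.78). By limma's variance test 0 of 14158 genes differed between cultures (0 at an unadjusted p under 0.05, smallest adjusted p = 0.457), and among the 3940 tested genes with 3 different values 0 passed and 184 had an unadjusted p under 0.05. After quantile normalization 0 passed this test and 864 (6.10%) had an unadjusted p under 0.05. After median centring it was 0 and 686 (4.85%), and after cyclic loess 0 and 585 (4.13%). These shares lie near the threshold of 0.05. The prior variance they rest on was fitted to the same genes, so they do not show whether cultures differed. The test recovered 0 of the changes added to the values as deposited, so the count of 0 does not show that cultures were alike.

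The 20 genes with the largest variance ratios, none of which passed the test, included protein-coding, small RNA and predicted genes. In 11 of the 20, culture 2 was lowest and culture 3 highest. The reference levels of unspecific signal had the same order (5.53, 5.63 and 5.71 on arrays 2, 1 and 3). Defa34 is a defensin gene, of a family used in the other reference set. Cox7b, a subunit gene of cytochrome oxidase, had 12.54, 11.92 and 12.44, the ribosomal gene Rps26 12.55, 12.64 and 12.43, and the microRNA gene Mir761 9.29, 8.51 and 9.91 for cultures 1, 2 and 3. Ranges over 1 log2 unit were found for Mir761 (1.40), Gm6625 (1.05), Defa34 (1.62), Gm7138 (1.31), Gm6981 (1.12), Mir1956 (1.17), Gm14407 (1.20), Lce3c (1.60) and Phf11a. The others, Mir449b, 6820431F20Rik, Gm20091, Rpl3, Snora21, Gm19399, Slc36a4, Mir1195 and Sarnp, had ranges between 0.20 and 0.90. No list of the 30 tested moved between cultures more than random lists of like signal. The largest SD of a list mean was 0.047 log2 units, for the mature neuron list (adjusted p = 0.928 against random lists). This largest SD and its list depended on the setting. It was 0.032 without replicate 2, 0.075 without replicate 1 (ependymal list) and 0.092 for genes with 3 different values (neurogenic programme list). The Notch and mural lists had smaller SDs than random lists (adjusted p = 0.00900 for both), and neither passed after quantile normalization, after cyclic loess or with any replicate left out.

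The direction of the difference between cultures 2 and 3 depended on the signal. Culture 1 held the middle value in 4427 of the 5534 genes with 3 different values (80.0%). Among receptor genes of the upper 50% by signal that differed between the arrays, 75% were higher on array 3. Among other genes above the reference level that differed, 19% were higher on array 3. With equal values counted in, the mean of array 3 minus array 2 was 0.13 ± 0.32 (SD over genes) for these receptor genes and -0.032 ± 0.17 for the other genes, and 0.11 and -0.0031 after cyclic loess.

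**Figure D3:**
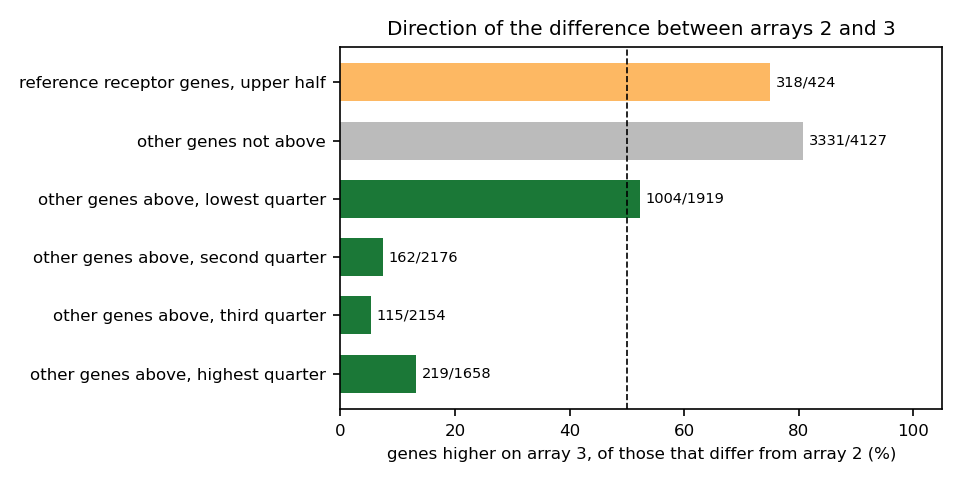
Percent of genes higher on array 3 than on array 2, among genes whose values differ (horizontal axis), by set, with the numbers beside the bars; genes above the reference level are split into 4 sets of equal size by mean signal. The dashed line marks 50%; receptor genes (75%) and other genes not above (80.7%) lie to its right and the upper 3 sets (7.44, 5.34 and 13.2%) to its left.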

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

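The tests of rounding, joint summarising, few distinct values, male animals, signal range, change of sign and cell makeup were chosen only after the results were seen. Signal was also found outside the named genes. Of the probe sets with no gene symbol, 6234 (38.9%) lay above the reference level on every array, as did 1093 (60.3%) of those with several symbols. Control probe sets of the array were not told apart from unnamed transcripts. No control samples were used here to set either share against.

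Exactly equal values on 2 or 3 arrays were found in 62.7% of probe sets. Rounding is argued against, since 98.3% of the values had 8 or more decimals. Summarising the 3 arrays together by median polish, the last step of RMA, stays open: 38.4% of probe sets whose value occurred once on array 1 had that value on another array too, and 14% on both others, but these shares are part of the pattern and cannot test it. For the 20398 such probe sets compared, chance sharing of few values is argued against. The next probe set by rank held such a value on another array in 0.0049% of cases at most. For the other probe sets it stays open, since 43.2 to 50.7% of the probe sets of an array shared their exact value with another there. A first version of the test of joint summarising took equality with the next probe set by rank over all probe sets, 30.9% at most, with a bound of 1%. It went against joint summarising and was replaced after its outcome was seen, because values shared within an array set it. No biological explanation was tested.

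Xist and 3 Y-linked genes were detected together on all 3 arrays. Male animals alone are argued against, since Xist was above the reference level on each array, with a smallest margin of 5.34 log2 units that, being set against other probes, shows detection and no amount. Unspecific signal is argued against too, since 0.0719% of receptor genes reached the lowest of the 4 signals, 9.23. Female animals alone, with Y-linked probes reading X-linked copies, cannot be told apart from a mixture: both measured X-linked copies, Kdm5c (10.41) and Kdm6a (10.36), were above the reference level (2 of 2), and Eif2s3x was not analysed here. RNA of both sexes on each array, from several pups, also stays open and was not tested.

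Culture 1 held the middle value in 80.0% of genes with 3 different values, and the difference between arrays 2 and 3 changed sign with the signal. A smooth shift of whole arrays is argued against as the whole cause of the middle position, which culture 1 kept in 69.1% of those genes after cyclic loess and 65% after quantile normalization. For the change of sign it stays open: after cyclic loess the mean of array 3 minus array 2 went from -0.032 to -0.0031 in other genes above the reference level, as loess brings about by construction, and from 0.13 to 0.11 in the receptor genes. More unspecific signal on array 3 stays open too, because the shares that led to this idea, 75% of receptor genes and 19% of other genes above the reference level higher there, cannot also test it. Different cell makeup cannot be told apart from chance, since 0 of 12 cell type lists moved more than random lists and a small shift could be missed, and differences between animals were not tested.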

How the results depend on the processing

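For detection, the alternatives with robust eBayes, with 1 prior variance, with members in no other list and with gene families at the 99th percentile were chosen only after the data were seen, as were those with 3 different values. No paired analysis was possible because there is 1 group. The number of genes above the reference level ranged from 9630 (other reference genes) to 14790 (90th percentile) around 13102, and from 12502 to 13022 with a replicate left out. Of 288 named genes 207 were called above. Of these, 40 lost the call at the 99th percentile and 40 with the other reference genes, and 30 more genes gained it at the 90th. Eif4enif1 was above under all these settings. Centring on the median leaves detection the same by construction.

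Lists below the other genes went from 6 to 2 and passing pairs from 8 to 3 at the 90th percentile. Differences from other genes that changed sign, never past the threshold, were: interferon 33.3% above at the 99th percentile and 33.3% with the other reference genes; NMDA receptor genes 16.7% and developmental timing genes 33.3% at the 99th; neurogenic programme 72.2%, mature neuron 77.8% and dorsal 81.8% at the 90th; neurogenic programme 44.4% and dorsal 45.5% with the other reference genes; dorsal 66.7% and ventral 62.5% with members in no other list. With the other reference genes the neuroblast (adjusted p = 0.152) and choroid plexus (0.120) lists lost their calls and immediate early genes gained one (0.0431). Without predicted genes in the background neuroblast lost its call (0.0663) and red blood cell markers gained one (0.0470).

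The lowest correlation between arrays was 0.988 over all probe sets, against 0.996, and 0.996 to 0.998 with a replicate left out. The 2 lists with a small spread became 0 after quantile normalization, median centring, cyclic loess, the median over probe sets, with 3 different values, and with any replicate left out (0 to 0). The Notch list's SD was then 0.022 after quantile normalization and 0.015 after cyclic loess. No gene passed the variance test under any of its 12 alternatives. Genes with an unadjusted p under 0.05 in this test numbered 864 (6.10%) after quantile normalization, 686 (4.85%) after median centring and 585 (4.13%) after cyclic loess, against 0. These shares lie near the threshold of 0.05, but the prior variance was fitted to the same genes, so they do not show whether cultures differed. The prior degrees of freedom were 1.86, 1.57 and 1.18, against 0.311 in the main fit, where such a p is hardly within reach. Added changes were not recovered in the values as deposited, and were not tried in the rescaled values. The causes were not tested. Signals near the reference level limit detection, and lists with under 3 members above (red blood cell, choroid plexus, Hox) gave no spread.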

Other observations

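The gene families here were chosen by symbol only after the data were seen, and their tests are adjusted over 21 families. All 22 measured Polycomb genes, which encode repressors of developmental genes, were above the reference level (Fisher's exact test, adjusted p = 3.12e-04), among them the histone methyltransferase gene Ezh2 (10.91), Suz12 (9.28), Eed (8.55 ± 0.027), Rnf2 (10.82) and Bmi1 (6.58 ± 0.12). Of 29 semaphorin and plexin guidance genes, 25 were above (adjusted p = 0.0384), including Sema6a (11.06 ± 0.025), Sema6d (11.32 ± 0.11), Plxnb1 (10.13) and Plxnb2 (10.45), while Sema3c (5.61) and Sema3e (5.03 ± 0.059) were not. Of 21 ephrin and Eph receptor genes 18 were above (adjusted p = 0.0920), with Epha4 at 9.40 ± 0.11 and Efna2 at 8.88.

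Neurotransmitter receptor genes were present in part. Of 9 AMPA and kainate receptor genes 8 were above (adjusted p = 0.220), including Gria2 (11.18), Gria3 (9.31), Grik2 (10.07) and Grik3 (10.01), with Grik1 (5.46) not above. Of 16 GABA-A receptor genes 10 were above (adjusted p = 1), with Gabrg1 at 11.16 and Gabra6 not above at 3.91. Of 6 NMDA receptor genes 4 were above (adjusted p = 1). Nicotinic receptor genes were less often above than other genes (5 of 16, adjusted p = 0.0498), and the lower shares of metabotropic glutamate (2 of 7, 0.197) and of serotonin and dopamine receptor genes (7 of 19, 0.0783) did not pass the threshold. Of 21 imprinted genes 17 were above (adjusted p = 0.197), including Nnat (11.96 ± 0.044), Mest (10.34) and Peg3 (10.18). Of 6 developmental timing genes 5 were above (adjusted p = 0.492), namely Lin28a (5.99 ± 0.031), Hmga2 (6.28), Igf2bp3 (8.94 ± 0.062), Dis3l2 (9.21) and Trim71 (5.81), and Lin28b (4.24) was not. Lin28a, Hmga2 and Trim71 lay near the reference level, and with the 99th percentile as reference they were no longer above, which left 2 of 6. Keratins (9 of 53, adjusted p = 2.00e-10), genes with interleukin symbols (6 of 37, 5.44e-08, counting the receptor genes Il7r, Il9r, Il21r and Il23r, none of them above), P450 family 2 genes (8 of 47, 1.59e-09) and chemokines (13 of 34, 0.0173) were less often above than other genes. With the 99th percentile, an alternative chosen after the data were seen, the Polycomb genes (18 of 22, adjusted p = 0.00595, Bmi1 no longer above) and the semaphorin and plexin genes (21 of 29, 0.0207) kept their calls and nicotinic receptor genes lost theirs (5 of 16, 0.273). Serotonin and dopamine receptor genes (1 of 19, 3.31e-04), potassium channel genes (21 of 86, 5.63e-05) and Wnt ligand genes (3 of 19, 0.0132) were then called less often above, while AMPA and kainate (7 of 9), GABA-A (5 of 16), NMDA (1 of 6) and metabotropic glutamate (2 of 7) receptor genes had no call.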
